A study of Mus musculus with 2744 samples.

How the data were processed

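Single-cell RNA sequencing was done by the study on 2744 mouse cells from 2 experiments, main and pilot, sampled on Days 2 to 6 of the differentiation of embryonic stem cells into motor neurons. The deposited tables, 1 per plate, hold counts of reads per gene and cell, not normalised. Per the labels, TopHat2 2.1.1 and HTSeq 0.6.1 were used on mm10; which step each carried out is not given in the sources used here. The counts are whole numbers without molecular identifiers, so duplicates from amplification are part of them. Each of the 35 tables used has 24092 entries: 23968 genes, of which 10 carry only a transcript identifier, 92 spike-in sequences, 5 summary lines of the counting step, and 27 gene names that are not written alike in every table because a spreadsheet had turned them into dates. Those 27 were left out. The summary lines took 34.9% of reads: 25.4% did not align uniquely, 7.48% met no feature and 2.04% were ambiguous. Spike-in sequences took 6.16%. The tables name genes and have no header, so a column was assigned to the day and experiment of its plate and not to a single cell's label. The 40 columns of 1 further table matched no sample, and they were used in no step. No kept cell had the same counts as another.

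A cell entered the sums if at least 500 genes had 1 or more reads, which kept 2448 cells and left out 296. Reads were summed over the cells of each group and experiment. The replicate is the experiment, since cells of a culture are not independent, and each group therefore has 2 sums. The Day 6 eGFP+ cells, from 1 plate of the main experiment, stayed outside the fit. The 12 other sums were fitted in R 4.3.3 with edgeR 4.0.16: filterByExpr, which left 16080 genes, TMM scaling, and a quasi-likelihood model of group plus experiment with 5 residual degrees of freedom. The common dispersion was 1.12 and the prior count for log2 changes 0.125. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes in each of 6 comparisons and a threshold of 0.05. The experiment was a term because each experiment had its own plate format. As a check, the log2 differences of main and pilot sums within 1 group correlated across the tested genes with those of another group at 0.0326 to 0.143 (median 0.103 over 15 pairs of groups).

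The choice of tests, gene lists, markers and alternatives was made before the data were examined, except for the alternatives and tests named as added later. The 27 gene lists were written by hand and 26 of them had at least 3 tested members; the list of transcripts of the mitochondrial genome had none. Each list was tested with camera (limma 3.58.1) against the other genes with a preset inter-gene correlation of 0.01, and adjusted over the 26 lists of a comparison. Members called over all genes and members adjusted over the list alone were counted. Some genes stand in 2 or more lists, such as Lhx3 and Nefm. List medians are medians of log2 ratios of CPM within an experiment, with sums under 3 reads set to 3 reads. A median equal to the ratio of the 2 floors is set by depth and is not given. Lower bounds of a fold use the same floor per sum. A detected gene held a median of 13 reads in a main and 73 in a pilot cell, more than this floor. These folds thus bound the ratio of reads and not that of molecules or cells.

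Genes named in the text follow a rule. For Day 6 against Day 2 and eGFP++ against Day 6 these are the 10 largest rises and falls, and for the other comparisons the 5 largest, among genes with adjusted p under 0.05, the same direction in both experiments, at least 20 CPM in the higher group and an established name. For each list, up to 2 members with the smallest adjusted p and up to 2 that changed the opposite way, or else the 2 best measured ones that did not pass, were added, as were the 18 markers.

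For shares of cells, each kept cell was thinned at random to 10000 reads, the largest depth of a series of 500, 1000, 2000, 5000 and 10000 that kept at least 70% of the filtered cells of each experiment. It kept 99.3% of main and 99.7% of pilot cells. The slope of a share on the day was tested with an exact permutation of the 5 days within each experiment (14400 permutations, two-sided), adjusted over the 18 markers. Intervals of shares are 95% Wilson intervals, and a share of 0 is given with the limit that 3 counts would set. The relation between 2 lists across cells is Spearman's rho between summed thinned reads within a day and experiment. For eGFP+ cells, medians of log2 ratios were compared with those of 10000 random lists matched on expression. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these steps, and coordinates came from GENCODE M21.

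The gene and list tests were run on simulated sums of the same depth. For Day 6 against Day 2, 0, 5, 30 and 43 of 50 genes changed by 2, 4, 16 and 64-fold were called, all in the right direction, with 9 of the unchanged genes among 15759 called. For Day 4 against Day 3 the counts were 0, 2, 34 and 48 of 50, with 2 unchanged genes called. A list moved by 4-fold was called and 0 of 25 unmoved lists were. Genes were drawn independently of each other there, and without a difference between the experiments. False calls of lists that come from correlation between genes could therefore not appear. The share test was run on simulated shares with normal noise, without cells or reads. It passed in 6% of 200 draws without a slope and in 99.5% of 200 draws with a slope of 10 points per day. Absence of a call thus says little about changes of 4-fold or less.

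The alternatives were DESeq2 1.42.0, as size factors and as a test, no filter on low counts, other cell filters, no experiment term, a fit of only the 2 groups compared, leaving out each sum, sums per plate, and cells thinned before summing. For lists they were camera with an estimated correlation, fry, no experiment term and all cells. For shares they were a smaller depth, no thinning, a detection limit of 2 reads and each experiment left out. Added after the data had been seen were counts of cells with a read in place of reads, and each experiment alone with plates as units. A fit without 3 plates with a median under 1200 detected genes per well over all wells was also added then. These plates held Day 3 cells of the main experiment and Day 4 cells of both experiments.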

Results

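The data were single-cell RNA sequencing of 2744 mouse cells, taken on Days 2 to 6 while embryonic stem cells were differentiated into motor neurons in culture. Each cell was 1 sample, sorted into 1 well, and its messenger RNA was amplified in a modified CEL-seq protocol, which tags the RNA of each cell with a barcode and amplifies it by transcription. The main experiment held 2304 cells on 24 plates and the pilot experiment held 440 cells on 11 plates. The labels named 7 groups: Days 2, 3, 4, 5 and 6 without an eGFP label, Day 6 eGFP++ in both experiments, and Day 6 eGFP+ on 1 plate of the main experiment. The labels did not say which reporter gave the eGFP signal. After wells with under 500 detected genes were left out, 2448 cells remained. In the main experiment the kept cells numbered 361 on Day 2, 422 on Day 3, 227 on Day 4, 332 on Day 5, 354 on Day 6, 83 in eGFP+ and 283 in eGFP++. In the pilot experiment they numbered 75, 69, 57, 75 and 71 on Days 2 to 6 and 39 in eGFP++. The summed gene reads of a group in 1 experiment ranged from 16370502 for the pilot eGFP++ cells to 100972780 for the main Day 3 cells.

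Depth and RNA yield per cell differed between the groups. The median number of detected genes per cell was 4439 on Day 2 and 2310.5 on Day 6 in the main experiment, and 1810 and 3361 in the pilot experiment. Spike-in RNA, added in the laboratory, took 2.98% of reads on Day 2 and 15.6% on Day 6 in the main experiment, and 4.75% and 15.4% in the pilot experiment. The reads carry no molecular identifiers, so a detected gene held a median of 13 reads in a main cell and 73 reads in a pilot cell. All intervals and limits given here therefore cover counting error only. Likewise, a fold given as at least some value bounds the ratio of reads and not that of molecules. Comparisons between groups used the reads summed over the cells of each group and experiment, so that n = 2 experiments per group. Values of log2 change are fitted by edgeR and given ± their standard error (SE). CPM is a gene's reads scaled to the total gene reads of the sum, with TMM scaling unless stated otherwise. Coordinates refer to GRCm38 (mm10).

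Adjacent days were compared to ask between which days groups of genes changed; no test compared 1 interval with another. With an estimated correlation between genes, camera called 1, 0, 0 and 0 lists in the 4 comparisons. Between Day 2 and Day 3, genes known to respond to retinoic acid rose as a group. Cyp26a1, which encodes an enzyme that degrades retinoic acid, went from 2.19 to 324 CPM in the main experiment and from 0.163 to 227 CPM in the pilot experiment. Hoxb5, a Hox gene of the hindbrain and cervical cord, and Crabp2, a carrier protein for retinoic acid, rose by 6.53 ± 0.51 and 4.61 ± 0.40 on the log2 scale (edgeR adjusted p = 0.000856 and 0.00137). Meis2, a partner of Hox proteins, rose by 7.98 ± 1.07 (adjusted p = 0.026).

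Among the 18 retinoic acid response genes, 4 rose and 14 did not pass over all genes, while 14 rose when adjusted over the list alone (camera adjusted p = 9.68e-20, kept with an estimated correlation at adjusted p = 0.0073). The list's median log2 ratio was 5.44 in the main and 3.26 in the pilot experiment. Of the 8 Hox genes of groups 1 to 3, 1 rose over all genes and 7 rose adjusted over the list alone, and the list rose as a whole (camera adjusted p = 1.63e-10; adjusted p = 0.0726 with an estimated correlation). The 15 Hox genes of groups 4 to 8 also rose as a list, with 1 gene called over all genes and 7 adjusted over the list alone (camera adjusted p = 3.09e-08; adjusted p = 0.217 with an estimated correlation). Their median log2 ratio was 6.21 in the main experiment. In the pilot experiment 7 of the 15 members had under 3 reads in both sums, and 7 of the other 8 were higher. Neural progenitor genes rose as a list of 22 with 0 called over all genes and 4 adjusted over the list alone (camera adjusted p = 0.0138; adjusted p = 0.342 with an estimated correlation). Their medians were 2.25 and 0.17.

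Genes of pluripotency and of the epiblast, the pluripotent tissue of the early embryo, fell as lists from Day 2 to Day 3. For the 28 pluripotency genes the medians were -1.98 in the main and -0.998 in the pilot experiment, with 0 members called over all genes and 0 adjusted over the list alone (camera adjusted p = 2.53e-08; adjusted p = 0.186 with an estimated correlation). For the 10 epiblast genes they were -3.13 and -1.25, with 0 called over all genes and 1 fallen adjusted over the list alone (camera adjusted p = 0.000325; adjusted p = 0.115 with an estimated correlation). Dnmt3b, a DNA methyltransferase of early embryonic cells, had a fitted log2 change of -3.54 that did not pass (adjusted p = 0.388). The 14 p53 target and apoptosis genes fell as a list with 0 members called (camera adjusted p = 0.00382; adjusted p = 0.115 with an estimated correlation), at medians of -0.94 and -0.59. The test gave a downward direction for pan-neuronal genes while their median and mean fitted changes were 0.47 and 0.51, and none of these tests passed (adjusted p = 0.884).

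In all, 8 of 16080 tested genes changed from Day 2 to Day 3, all of them upward and in the same direction in both experiments. The other called genes, named outside the rule after their values were seen, were H1f0, Metrn and Dach1, of which Dach1 lay at 0 reads in both Day 2 sums and at 6.41 and 10.7 CPM on Day 3. At an unadjusted p under 0.05 there were 587 genes, and DESeq2 called 166, of which 121 rose. The count was 0 without the Day 2 sum of the pilot experiment and 38 without that of the main experiment.

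From Day 3 to Day 4 camera called 5 lists with its preset correlation and 0 with an estimated one, and edgeR called 0 single genes. Glycolytic enzymes and glucose transporters fell as a list of 18, at medians of -0.68 in the main and -0.72 in the pilot experiment, with 0 members called over all genes or over the list alone. Slc2a1, a glucose transporter, and Ldha, which makes lactate, had fitted log2 changes of -0.92 ± 0.39 and -0.69 ± 0.29. Pluripotency genes fell as a list at medians of -0.60 and -1.26. Genes of the floor plate, the ventral midline tissue that releases Sonic hedgehog, rose as a list of 8 at medians of 1.60 and 3.05. Genes that respond to Hedgehog signalling and those of motor neuron progenitors rose as lists of 14 and 17, at medians of 1.25 and 0.93 in the main experiment. In the pilot experiment 4 and 6 members had under 3 reads in both sums, and 5 of the other 10 and 6 of the other 11 were higher. In each of these 2 lists 1 gene rose adjusted over the list alone, and it was Olig2, the transcription factor that specifies motor neuron progenitors. Olig2 went from 0 to 6.44 CPM in the main experiment, at least 208-fold higher in reads against a floor of 3 reads in the sum. With all reads used, it was found in 0% of 422 Day 3 and 8.37% of 227 Day 4 cells there. In the pilot experiment Olig2 stayed under the floor on both days. On Day 2 it had been at 1.97 and 3.17 CPM, at least 63.6-fold and 76-fold above Day 3.

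These lists passed camera at adjusted p = 0.00265 for glycolysis, 0.0104 for pluripotency, 0.0104 for the floor plate, 0.0182 for the Hedgehog response and 0.0389 for motor neuron progenitors. With an estimated correlation none passed: the adjusted p was 0.614 for glycolysis, pluripotency and motor neuron progenitors and 0.588 for the floor plate and the Hedgehog response. In lists that did not pass as a whole, Stmn2 and Gap43 among the pan-neuronal genes fell and Fos and Jun among the genes raised by dissociation rose adjusted over the list alone. Wells with under 500 detected genes were more frequent on Day 4, at 21.2% and 28.75% against 12.1% and 13.75% on Day 3. In the main experiment this came from a single Day 4 plate at 46.9%, with the others at 11.5% and 5.21%. The pilot Day 4 plates were at 40% and 17.5%. Kept cells had medians of 3114 and 1404 genes on Day 4 against 4145.5 and 1837 on Day 3. edgeR called 0 single genes from Day 3 to Day 4, with 432 at an unadjusted p under 0.05, and DESeq2 called 155. The count was 4 without the Day 3 sum and 8 without the Day 4 sum of the main experiment, and only the glycolysis list passed without 3 plates on which few genes were detected per well. With cells with a read counted, the glycolysis list did not pass (adjusted p = 0.3654) and the other 4 did.

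Between Day 4 and Day 5 genes of neurons and of motor neurons rose as lists. Isl1, a homeobox factor of newly born motor neurons, went from 0 to 91.2 CPM in the main experiment and from 0.0152 to 51.9 CPM in the pilot experiment. Gap43, a growth cone protein, went from 2.71 to 467 CPM and from 0.0608 to 108 CPM. Stmn2, which regulates microtubules in growing axons, had a fitted log2 change of 2.45 ± 0.38. None of the 3 passed over all genes (edgeR adjusted p = 0.651, 0.425 and 0.337), and their lists did.

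The 34 pan-neuronal genes rose as a list from Day 4 to Day 5, at medians of 2.55 in the main and 4.19 in the pilot experiment, with 0 called over all genes and 4 adjusted over the list alone (camera adjusted p = 1.69e-17; adjusted p = 0.169 with an estimated correlation). Motor neuron genes rose likewise, at medians of 2.48 and 4.97 and with 4 of 28 members adjusted over the list alone (camera adjusted p = 4.03e-08; adjusted p = 0.172 with an estimated correlation). Motor neuron progenitor genes rose at medians of 1.67 and 5.01, with Sox11 and Gadd45g passing adjusted over the list alone (camera adjusted p = 2.63e-06; adjusted p = 0.172 with an estimated correlation). Notch pathway genes rose at medians of 0.98 and 3.74 (camera adjusted p = 9.7e-06; adjusted p = 0.172 with an estimated correlation). Neural progenitor genes rose at medians of 1.02 and 1.63 (camera adjusted p = 0.000333; adjusted p = 0.172 with an estimated correlation). Hox genes of groups 4 to 8 rose at medians of 1.25 and 3.26 (camera adjusted p = 5.62e-06; adjusted p = 0.21 with an estimated correlation). Axon guidance genes rose at medians of 1.79 and 0.94 (camera adjusted p = 0.000289; adjusted p = 0.21 with an estimated correlation). In these 4 lists 0 members passed, over all genes or over the list alone.

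Pluripotency genes fell again from Day 4 to Day 5, at medians of -2.63 and -0.65 with 0 members called in either way (camera adjusted p = 9.7e-06; adjusted p = 0.21 with an estimated correlation). Neuronal RNA-binding protein genes rose as a list of 22, and 2 members, Elavl2 and Rbfox3, passed adjusted over the list alone (camera adjusted p = 0.00174; adjusted p = 0.169 with an estimated correlation). Their median was 1.37 in the main experiment. In the pilot experiment 4 members had under 3 reads in both sums, and 10 of the other 18 were higher. edgeR called 0 single genes, with 595 at an unadjusted p under 0.05, and DESeq2 called 186, of which 113 rose. The count was 15 without the Day 4 sum of the main experiment.

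From Day 5 to Day 6 the pan-neuronal list rose and the cell cycle list fell, both with the preset correlation only. The pan-neuronal list had medians of 2.09 and 2.76, with 34 and 33 of its 34 members higher in the main and the pilot experiment and 1 risen adjusted over the list alone (camera adjusted p = 3.4e-15; adjusted p = 0.132 with an estimated correlation). Stmn2 had a fitted log2 change of 3.06 ± 0.39 (edgeR adjusted p = 0.112). The 40 genes of S and G2/M phases fell as a list at medians of -1.10 and -0.78, and 0 and 2 of them were higher on Day 6 in the main and the pilot experiment (camera adjusted p = 4.31e-14; adjusted p = 0.111 with an estimated correlation). Hmgb2 and Cdk1, a chromatin protein of dividing cells and the kinase that starts mitosis, had fitted log2 changes of -1.31 ± 0.36 and -1.34 ± 0.46, and 0 of the 40 passed over all genes or over the list alone.

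Genes linked to leaving the cell cycle rose as a list of 12 at medians of 0.33 and 1.10, with 0 members called in either way (camera adjusted p = 0.00173; adjusted p = 0.132 with an estimated correlation). Cdkn1c and Cdkn1a, inhibitors of cyclin-dependent kinases, had fitted log2 changes of 1.90 ± 0.72 and 1.47 ± 0.59. Motor neuron genes rose at medians of 1.31 and 2.14 (camera adjusted p = 4.28e-05; adjusted p = 0.336 with an estimated correlation). Axon guidance genes rose at 0.78 and 2.23 (camera adjusted p = 2.8e-05; adjusted p = 0.205 with an estimated correlation). Ventral interneuron factors rose at 1.63 and 1.10 (camera adjusted p = 0.00573; adjusted p = 0.239 with an estimated correlation), but pointed down with cells with a read counted (adjusted p = 0.619). None of these 3 lists had a member called in either way. Pluripotency genes fell at medians of -1.39 and -2.80, with 4 fallen adjusted over the list alone (camera adjusted p = 1.56e-13; adjusted p = 0.132 with an estimated correlation). edgeR called 0 single genes, with 510 at an unadjusted p under 0.05, and DESeq2 called 129.

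**Figure D1:**
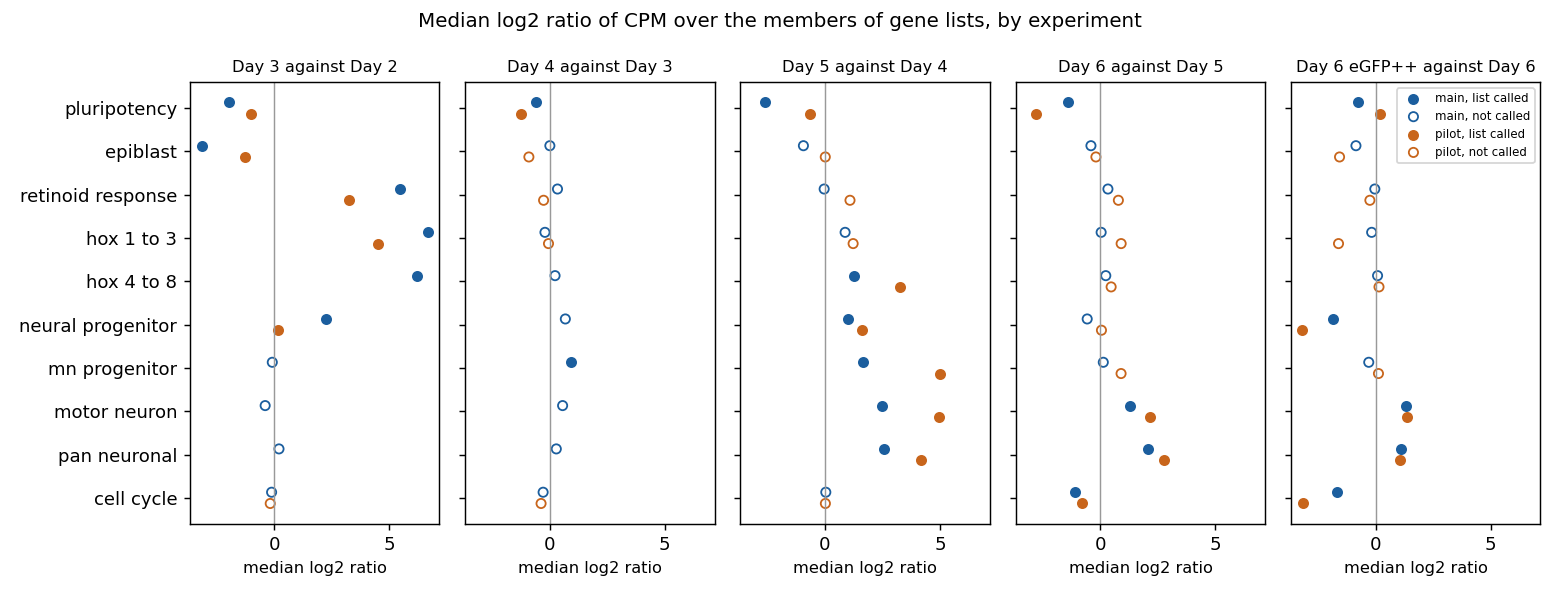
Median log2 ratio of CPM over the members of 10 gene lists (x axis) for 5 comparisons, in the main and the pilot experiment; filled points mark lists that camera called with its preset correlation, and medians set by the floor of 3 reads are not drawn. The retinoic acid response list lies at 5.44 and 3.26 on Day 3 against Day 2, and the cell cycle list at -1.67 and -3.14 in eGFP++ against Day 6.

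Over the whole course, Day 6 against Day 2, stem cell genes fell as a list and genes of neurons, motor neurons and Hox groups 1 to 8 rose. With an estimated correlation 3 of these lists did not pass, at adjusted p = 0.0591 for neurons, 0.0675 for motor neurons and 0.0743 for Hox groups 4 to 8. Dppa5a, an RNA-binding protein of embryonic stem cells, went from 3291 to 7.27 CPM in the main experiment and from 1977 to 15.97 CPM in the pilot experiment. Tdgf1, a co-receptor for Nodal, went from 442 to 0.0502 CPM and from 595 to 0.0319 CPM. Celf3, a splicing regulator of neurons, lay at 0 reads in both Day 2 sums. Its Day 6 reads were at least 2381-fold and 1401-fold higher, against a floor of 3 reads per sum. Such folds bound reads, not molecules. Slc18a3, which loads acetylcholine into vesicles, went from 0.196 to 72.6 CPM in the main experiment and from 0 reads to a level at least 1280-fold higher in the pilot experiment. Hoxb5 had the smallest adjusted p, at 0.000201 (edgeR), and went from 2.101 to 483 CPM and from 1.503 to 414 CPM.

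Of 16080 genes, 94 rose and 40 fell from Day 2 to Day 6, all 134 in the same direction in both experiments. The balance of rises and falls depended on the method: 1303 and 732 with DESeq2, 1716 and 1824 with cells with a read counted, 258 and 250 in a fit of the 2 groups alone, 1886 and 1873 in the main experiment alone, and 141 and 15 without the Day 2 sum of the main experiment. The largest rises were those of Celf3, Dach1, Hoxd3, Scg2, Hoxa3, Th, Tmem132e, Cyp26b1, Hoxc5 and Lhx1, with adjusted p from 0.000403 to 0.046. They lay at 3 reads or fewer per sum on Day 2, except Cyp26b1 at 0.168 CPM in the main experiment, so that their fitted changes of 12.79 to 16.27 depend on the prior count. On Day 6 their levels ran from 26.3 CPM for Scg2 in the pilot experiment to 607 CPM for Cyp26b1, an enzyme that degrades retinoic acid. Th, the first enzyme of dopamine synthesis, reached 178 and 88.3 CPM, and Lhx1, a homeobox factor of lateral motor neurons and interneurons, 65.3 and 27.8 CPM. The largest falls were those of Fam25c, Tdgf1, Anxa8, Lefty1, Trh, Dppa3, Etv5, L1td1, Dppa5a and Dnmt3b, with fitted changes of -15.37 to -7.87 and adjusted p from 0.0032 to 0.0461. Fam25c lay at 66.03 and 83.2 CPM on Day 2 and at 0 reads on Day 6, at least 1316-fold and 1738-fold lower.

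Retinoic acid response genes were higher on Day 6 in all 18 members in the pilot experiment and in the 17 that had at least 3 reads in a sum of the main experiment; 9 rose and 9 did not pass over all genes, and 13 rose adjusted over the list alone (camera adjusted p = 6.26e-16). Crabp2 rose by 5.11 ± 0.41 and Meis2 by 9.24 ± 1.13. Of the 8 Hox genes of groups 1 to 3, 5 rose, and 7 adjusted over the list alone (camera adjusted p = 9.52e-09). Of the 15 Hox genes of groups 4 to 8, 7 rose, among them Hoxb8 by 10.51 ± 1.39, and 11 adjusted over the list alone (camera adjusted p = 2.83e-11; adjusted p = 0.0743 with an estimated correlation). Hox genes of groups 9 to 13 did not pass as a list of 10 (camera adjusted p = 0.81), and 1 of them rose adjusted over the list alone. The list medians in the main and the pilot experiment were 5.08 and 5.43 for the retinoic acid response, 7.50 and 9.37 for Hox groups 1 to 3, and 8.16 and 8.10 for groups 4 to 8. For groups 9 to 13 it was 0.90 in the main experiment, and in the pilot experiment 8 of the 10 members had under 3 reads in both sums.

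Among 28 pluripotency genes 8 fell, 20 did not pass over all genes and 20 fell adjusted over the list alone, at medians of -5.93 and -6.34 (camera adjusted p = 4.1e-24). Sall4, a zinc finger factor of stem cells, fell by 3.59 ± 0.42 on the log2 scale and Zfp42 by 6.21 ± 0.98. Pou5f1, the central factor of pluripotency, went from 672 to 0.0334 CPM in the main experiment and from 391 to 11.2 CPM in the pilot experiment, and did not pass (-8.43 ± 1.963, adjusted p = 0.0906). Among 10 epiblast genes 1 fell over all genes, Dnmt3b, and 6 fell and 1 rose adjusted over the list alone (camera adjusted p = 1.82e-06). The one that rose was Sox3, which is also a neural progenitor gene. The epiblast medians were -5.93 and -3.87.

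Of the 34 pan-neuronal genes, 3 rose over all genes and 24 adjusted over the list alone, at medians of 5.58 and 6.53 (camera adjusted p = 6.75e-16; adjusted p = 0.0591 with an estimated correlation). Stmn2 rose by 2.94 ± 0.38 and Stmn3 by 7.24 ± 1.33. Of the 28 motor neuron genes, 2 rose, Lhx1 and Slc18a3, and 11 adjusted over the list alone, at medians of 3.66 and 6.41 (camera adjusted p = 4.97e-09; adjusted p = 0.0675 with an estimated correlation). Isl1 did not pass (adjusted p = 0.41), with 0.616 CPM on Day 2 in the main and 18.5 CPM in the pilot experiment. Of the 32 axon guidance genes, 2 rose, Unc5a by 8.70 ± 1.65 and Nrcam by 6.36 ± 1.22, and 15 adjusted over the list alone (camera adjusted p = 1.95e-10). Among 22 neuronal RNA-binding protein genes 1 rose, Celf3, while 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000553). The one that fell was Ptbp1, a splicing repressor of non-neuronal cells, at -1.60 ± 0.37.

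Progenitor genes were higher too. Of 22 neural progenitor genes, 2 rose over all genes and 11 adjusted over the list alone, at medians of 2.98 and 2.60 (camera adjusted p = 1.06e-07). Hes5, a target of Notch, rose by 9.98 ± 1.48 and Vim, an intermediate filament of progenitors, by 2.77 ± 0.45. Motor neuron progenitor genes had 1 riser of 17, Sox11, and 8 adjusted over the list alone (camera adjusted p = 1.24e-06; adjusted p = 0.109 with an estimated correlation). Notch pathway genes had 1 riser of 19, Hes5, and 4 adjusted over the list alone (camera adjusted p = 2.59e-05; adjusted p = 0.112 with an estimated correlation). Interneuron factors and floor plate genes rose as lists of 17 and 8 with 0 members called in either way (camera adjusted p = 0.00353 and 0.0104; adjusted p = 0.0743 and 0.256 with an estimated correlation, and 0.656 and 0.149 with cells with a read counted). The 40 cell cycle genes fell as a list at medians of -1.31 and -1.36, with 0 called over all genes and 11 adjusted over the list alone (camera adjusted p = 2.87e-12). Genes linked to leaving the cell cycle rose at medians of 1.82 and 1.91, with 0 over all genes and 5 of 12 adjusted over the list alone (camera adjusted p = 0.000435).

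Lists of other lineages and states did not pass in Day 6 against Day 2. Camera's adjusted p was 0.134 for glia, 0.726 for neural crest, 0.457 for primitive streak and mesoderm, 0.786 for endoderm, 0.12 for the Hedgehog response, 0.108 for glycolysis and 0.134 for apoptosis, with 0 members called over all genes. In the DNA methylation and chromatin list (adjusted p = 0.323), Dnmt3b and Suz12, a subunit of Polycomb complex PRC2, fell, and adjusted over the list alone 4 rose and 6 fell. That list's median fitted change was -0.45 and its mean 0.31. In the dissociation list (adjusted p = 0.68), Jun rose by 3.58 ± 0.62 and Hsp90aa1, a heat shock protein, fell by 2.08 ± 0.31. With cells with a read counted Hsp90aa1 did not fall (0.0326), and 132 of all 134 called genes kept their direction. The neural crest list had medians of -1.01 and 0.55, which differ in sign between the experiments. The list of transcripts of the mitochondrial genome had no tested member.

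Of the 16 lists called in Day 6 against Day 2, 9 held with an estimated correlation, at adjusted p = 0.0203 for the retinoic acid response and 0.0444 for the others. The 3 plates of few detected genes, left out in 1 fit below, held Day 3 and Day 4 cells only. Leaving them out can move the count of genes only through the fit shared by all groups. At an unadjusted p under 0.05 there were 2206 genes, and DESeq2 called 2035, which included all 134. The count was 8 without the Day 2 sum of the pilot experiment, 44 without the Day 6 sum of the main experiment, 21 without that of the pilot experiment, and 76 without 3 plates of few detected genes.

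The eGFP++ cells of Day 6 were compared with the Day 6 cells without an eGFP label, called unselected here, to ask which transcripts set them apart. Genes of dividing and of progenitor cells fell as lists, and with an estimated correlation the former passed and the latter did not (adjusted p = 0.0244 and 0.219). Ccnd1, the cyclin that drives cells through G1, was at 3.30 against 99.3 CPM in the main experiment and 3.50 against 60.2 CPM in the pilot experiment. Sparc, a secreted matrix protein, was at 1.82 against 122 CPM and at 1.03 against 58.4 CPM. Genes of neurons and of motor neurons rose as lists with 0 members called, and neither list passed with an estimated correlation (adjusted p = 0.421 and 0.447). Gap43 was at 4516 against 1729 CPM and 4924 against 1159 CPM, and Lhx3, a factor of motor neurons, at 322 against 100.5 CPM and 299 against 109 CPM.

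Egfp itself was at 9759 against 3804 CPM of all gene reads in the main and 4413 against 2709 CPM in the pilot experiment, and was found in 99.6% and 97.4% of eGFP++ cells and in 55.1% and 59.2% of unselected cells at 10000 reads per cell. Its log2 change did not pass (0.90 ± 1.98, adjusted p = 0.932). As a background, Egfp was found in 11.8% of Day 2 cells of the main experiment (95% Wilson interval 8.87% to 15.6%) and in 0 of 74 Day 2 cells of the pilot experiment, which allows a share of up to 4.05%.

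All 5 called genes fell. Sparc fell by 5.96 ± 0.60 on the log2 scale, Fbxo5, an inhibitor of the anaphase-promoting complex, by 5.91 ± 0.67, and Upp1, which breaks down uridine, by 4.95 ± 0.48. Ccnd1 fell by 4.47 ± 0.61 and Cdca7, a chromatin protein of cycling cells, by 4.15 ± 0.57. The adjusted p was 0.00614 for Sparc and Upp1, 0.0135 for Fbxo5 and 0.0479 for Ccnd1 and Cdca7 (edgeR). Ccnd1 stands in the list of genes linked to leaving the cell cycle, which did not pass as a whole (camera adjusted p = 0.987).

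The 40 cell cycle genes fell as a list in eGFP++ cells, at medians of -1.67 in the main and -3.14 in the pilot experiment, with 0 called over all genes and 29 adjusted over the list alone (camera adjusted p = 1.51e-24, kept with an estimated correlation at adjusted p = 0.0244). Mki67 and Pcna, markers of proliferation and DNA replication, had fitted changes of -4.21 ± 0.74 and -1.78 ± 0.32. Neural progenitor genes fell at medians of -1.83 and -3.18, with 7 of 22 adjusted over the list alone, among them Sox2 at -3.88 ± 0.75 (camera adjusted p = 5.32e-05; adjusted p = 0.219 with an estimated correlation). Pan-neuronal genes rose at medians of 1.10 and 1.06, with 32 and 29 of 34 members higher and 0 called in either way (camera adjusted p = 9.15e-05; adjusted p = 0.421 with an estimated correlation). Motor neuron genes rose at 1.32 and 1.39 (0.897 in the pilot experiment without 3 members under 3 reads in both sums), with 0 called in either way (camera adjusted p = 0.00215; adjusted p = 0.447 with an estimated correlation). In this comparison DESeq2's size factors shifted the median of all genes by 0.13 on the log2 scale relative to TMM.

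Some lists of other cell types were lower in the eGFP++ cells, while those of glia, of neural crest and of primitive streak and mesoderm did not pass (camera adjusted p = 0.921, 0.987 and 0.1645). Interneuron factors fell at medians of -3.02 and -2.31 with 0 members called in either way (camera adjusted p = 0.000623; adjusted p = 0.27 with an estimated correlation). Endoderm genes fell at -1.97 and -3.11, with Sparc called over all genes and 3 of 19 adjusted over the list alone (camera adjusted p = 0.00143; adjusted p = 0.196 with an estimated correlation). Notch pathway and floor plate genes fell with 0 members called in either way (camera adjusted p = 0.019 and 0.0431; adjusted p = 0.447 with an estimated correlation for both), and the latter list did not pass with cells with a read counted (adjusted p = 0.0625). Pluripotency genes fell, with 4 adjusted over the list alone (camera adjusted p = 0.00143; adjusted p = 0.421 with an estimated correlation). Their medians were -0.74 and 0.21, and -1.36 and -1.286 without the 5 and 8 members with under 3 reads in both sums. Spike-in RNA took 11.9% and 10.8% of reads in eGFP++ cells against 15.6% and 15.4% in unselected Day 6 cells. The main eGFP++ plates were split, at 9.39%, 8.97% and 18.4%, against 13.9% to 16.9% on unselected Day 6 main plates. The pilot eGFP++ cells came from 1 plate. The 3 plates of few detected genes, left out in 1 fit below, held no Day 6 cells and act here only through the shared fit. Beside the 5 genes called, 1011 were at an unadjusted p under 0.05 and DESeq2 called 514, of which 450 fell. The count was 0 without the eGFP++ sum of the pilot experiment, which held 39 cells, 761 without that of the main experiment, 3 and 2 without the Day 6 sum of the main and the pilot experiment, and 2 without 3 plates of few detected genes.

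The Day 6 eGFP+ cells came from 1 plate of the main experiment and stayed outside the fit. Values are CPM of all gene reads, and percentiles place a list among random lists without a replicate. Neurog2, which drives progenitors to become neurons, was at 382 CPM, against 129 in unselected and 42.5 in eGFP++ cells. Top2a, a topoisomerase of dividing cells, was at 619 CPM against 523 and 98.8 CPM. Other genes of dividing and progenitor cells went both ways. Below the unselected cells lay Mki67 at 41.8 against 50.7 CPM, Sox2 at 36.5 against 67.4 CPM, Sox1 at 6.02 against 22.9 CPM and Olig2 at 36.7 against 42.6 CPM. Above them lay Ccnb1 at 373.8 against 191.8 CPM and Pax6 at 97.15 against 72.8 CPM. Nefm, a neurofilament, was at 332 CPM against 1049 and 3516 CPM, and Egfp at 1488 CPM against 3804 and 9759 CPM. The median log2 ratio of eGFP+ to unselected cells was -1.55 for motor neuron genes (percentile 0 among 10000 random lists of matched expression), -0.87 for pan-neuronal genes (percentile 0.01) and 0.27 for motor neuron progenitor genes (percentile 99.7). For cell cycle genes it was -0.193 (percentile 93) and for neural progenitor genes -0.536 (percentile 34.3). For eGFP++ against eGFP+ cells it was 2.78 for motor neuron genes and 1.79 for pan-neuronal genes (percentile 100 for both), and -2.04 for cell cycle genes (percentile 0). The eGFP+ plate had a median of 1524 genes per cell and a spike-in share of 19%.

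The share of cells with a marker changed with the day for most of the 18 markers (the plot of marker shares). Shares are given at 10000 reads per cell for Days 2 to 6 without eGFP selection, with 95% Wilson intervals drawn in that plot. Equal reads do not make detection equal, since reads include copies from amplification. On Day 2 kept cells had medians of 4439 genes in the main and 1810 in the pilot experiment. Pou5f1 was found in 95.5% of cells on Day 2 (interval 92.8% to 97.2%), 33.4% on Day 3 and 7.96% on Day 4 in the main experiment. On Day 6 it was found in 0 of 354 cells, which allows a share of up to 0.847%. In the pilot experiment the share went from 50% on Day 2 (interval 38.9% to 61.1%) to 2.82% on Day 6. On 1 Day 3 plate of the main experiment 0 cells had a Pou5f1 read at this depth. Neurog2 was found in 30.4% and 17.3% of cells on Day 5 and in 20.6% and 18.3% on Day 6, in the main and the pilot experiment. Isl1 was found in 20.2% and 14.7% of cells on Day 5, with 35.5% on 1 plate of the main experiment. In eGFP++ cells it was found in 53.9% and 28.2%. Pilot values of Day 5 pool unlike plates. With all reads used, Egfp was found in 10.5% of kept cells on 1 of them and in 64.9% on the other. Tubb3, a tubulin of neurons, went from 8.17% to 47.2% in the main and from 1.35% to 40.8% in the pilot experiment. Top2a went from 91.3% to 23.4% and from 70.3% to 47.9%.

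Of 18 markers, 14 had a slope on the day that passed an exact permutation test of the days within each experiment (14400 permutations, two-sided, adjusted over the 18). Falling shares were those of Pou5f1 at -17.4 points per day, Zfp42 at -6.26 and Top2a at -10.1. Rising ones were those of Hoxb4 at 9.83 points per day, Tubb3 at 9.77, Hoxc5 at 8.09, Elavl3 at 7.48, Crabp1 at 6.52, Neurog2 at 6.24, Pax6 at 6.22, Olig2 at 5.52, Isl1 at 5.24, Lhx3 at 5.05 and Mnx1 at 1.19. The permutation p of Pou5f1 and Zfp42 was 0.0001389, the smallest these permutations can give (adjusted p = 0.00125), and the largest adjusted p among the 14 was 0.0491 for Pax6. The slopes of Sox2 (-5.78, adjusted p = 0.0655), Stmn2 (2.70, adjusted p = 0.536), Sox1 (1.14, adjusted p = 0.559) and Mki67 (-0.231, adjusted p = 0.936) did not pass in the same permutation test. All 14 had the same sign in both experiments. A slope does not show the course between days. From Day 5 to Day 6 Pax6 fell from 50.3% to 23.2% in the main and from 24% to 11.3% in the pilot experiment. Olig2 fell from 26.1% to 18.9% and from 22.7% to 14.1%. Hoxb4, Hoxc5, Crabp1 and Neurog2 fell in the main and rose in the pilot experiment. Median genes per kept cell also fell in the main experiment, from 3614.5 to 2310.5, and rose in the pilot experiment, from 3122 to 3361. Whether detection moved these shares was not tested. Stmn2 was found in 45.1% and 12.2% of Day 2 cells, in 3.98% and 3.51% on Day 4 and in 46.6% and 38% on Day 6.

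**Figure D2:**
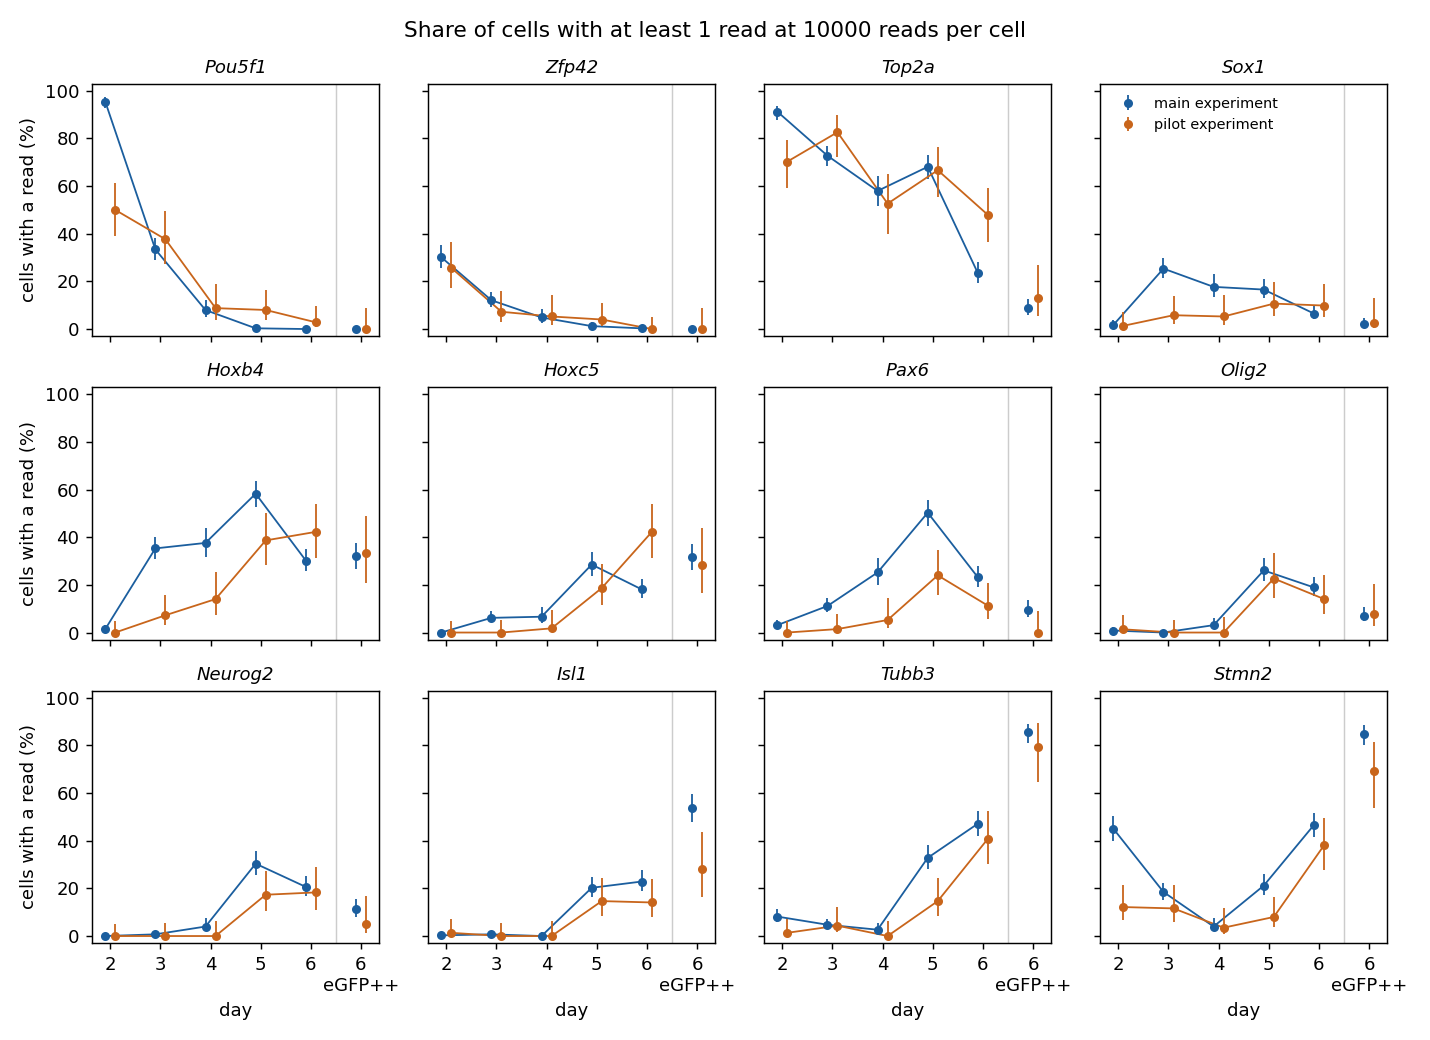
Share of cells with at least 1 read of 12 markers at 10000 reads per cell (y axis, percent) by day (x axis), with 95% Wilson intervals, for the main and the pilot experiment; points at the right are eGFP++ cells of Day 6. Pou5f1 falls from 95.5% and 50% on Day 2 to 0% and 2.82% on Day 6, and Tubb3 reaches 47.2% and 40.8%.

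On Day 6, cells rich in neuronal transcripts were poor in progenitor transcripts. Spearman's rho across cells between the summed reads of neural progenitor and pan-neuronal genes was 0.00378 in the main and 0.0185 in the pilot experiment on Day 2, when the pan-neuronal sum had a median of 3 and 0 reads per cell and rho had little room. It was -0.436 and -0.0238 on Day 5 and -0.702 and -0.509 on Day 6. Between cell cycle and pan-neuronal genes it was -0.011 and 0.0643 on Day 2, -0.331 and -0.167 on Day 5 and -0.504 and -0.427 on Day 6. Among eGFP++ cells rho was -0.411 and -0.268 for the former pair and -0.125 and -0.298 for the latter. Between pluripotency and pan-neuronal genes it stayed within -0.172 and 0.216 on all days. Cells of a culture are not independent replicates, so no p is given.

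**Figure D3:**
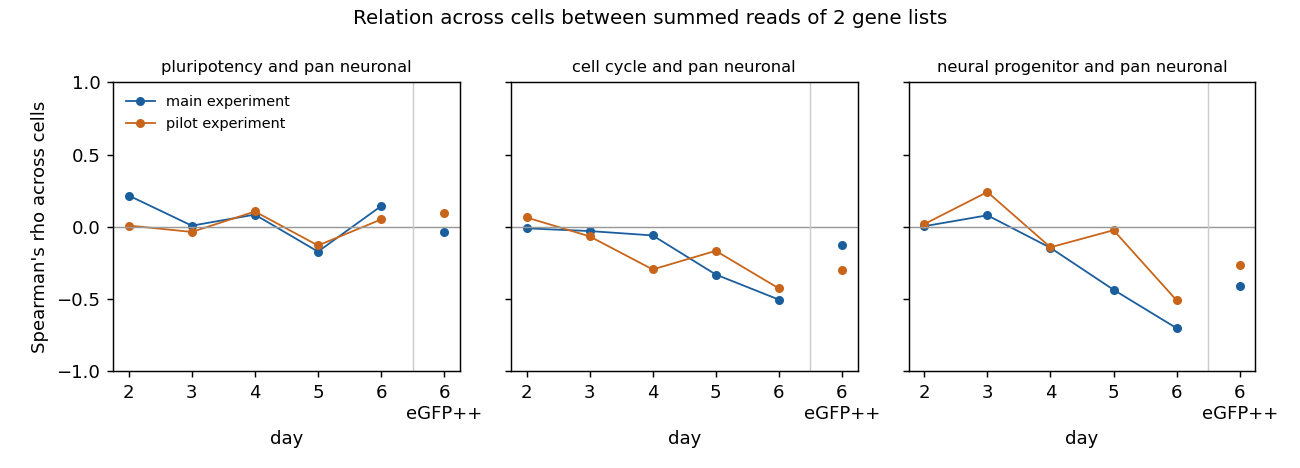
Spearman's rho across cells (y axis) between the summed reads of 3 pairs of gene lists by day (x axis), in the main and the pilot experiment, with eGFP++ cells of Day 6 at the right. The neural progenitor and pan-neuronal pair reaches -0.702 and -0.509 on Day 6.

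The experiments shared no library, so the agreement of their changes was measured across genes, which are not independent replicates. For Day 6 against Day 2, Pearson's r between the log2 changes of the main and the pilot experiment was 0.512 (Spearman's rho 0.487), and 67.9% of genes had the same sign. For the comparisons of adjacent days r ran from 0.0653 for Day 4 against Day 3 to 0.161 for Day 3 against Day 2, and for eGFP++ against Day 6 it was 0.104. Among genes with a mean of at least 20 CPM, r was 0.773 for Day 6 against Day 2.

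The main genes lie as follows, by chromosome, start and end. Cyp26a1 is on chromosome 19 from 37697798 to 37701536 and Hoxb5 on chromosome 11 from 96303336 to 96306121. Crabp2 is on chromosome 3 from 87948666 to 87953376 and Meis2 on chromosome 2 from 115863064 to 116065839. Celf3 is on chromosome 3 from 94478295 to 94492198, Dppa5a on chromosome 9 from 78367052 to 78368177, and Tdgf1 on chromosome 9 from 110939603 to 110946158. Sparc is on chromosome 11 from 55394500 to 55423183, Fbxo5 on chromosome 10 from 5799160 to 5805600, and Upp1 on chromosome 11 from 9118103 to 9136170. Ccnd1 is on chromosome 7 from 144929931 to 144939925, Cdca7 on chromosome 2 from 72476159 to 72486893, and Pou5f1 on chromosome 17 from 35506018 to 35510772.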

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

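All tests in this part were chosen only after the results had been seen. In sets of 4 or 5 plates of a day of the main experiment, 60 sets were searched for a plate far from the others. Of these 7 stood out, where chance gives about 1 in 20, or 3 of 60. The sets are measures of the same plates and are not independent, so 7 against 3 is no test. Most of the 7 fell on 1 Day 3 and 1 Day 5 plate.

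On 1 Day 3 plate the median number of genes per cell was 1220, against 3992 to 4724 on the other 4 plates. Pou5f1 was found in 0% of its cells, against 34.9% to 48.2%, and Top2a in 44.9%, against 73.9% to 82.7%. On 1 Day 5 plate the median was 4238 genes, against 3486 to 3570 on the other 3, with Isl1 in 35.5% of cells, against 14.5% to 16.3%, and Stmn2 in 31.6%, against 17.2% to 19.3%. On 1 Day 2 plate Mki67 was found in 9.30% of cells, against 26.1% to 29.6% on the other 3.

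For the missing Pou5f1 on the Day 3 plate, cells of Day 5 or Day 6 were argued against as the whole cause: the plate lay at -0.029 of the way to Day 5 and -0.0233 to Day 6, and its Egfp level was 4.04 CPM, against at least 1020 CPM on those plates. A bias against GC-rich transcripts stays open as a candidate explanation. The plate's ratios fell with GC content (rho -0.54). On the other 4 plates rho was 0.269 to 0.503. Each of those was set against a mean that held this plate, which shifts their rho upward, so they are no independent control. Pou5f1, at 57.6% GC, lay at percentile 2.97 of 303 genes of like GC content, whose median was -2.17. A general loss of transcripts cannot be told apart from a GC bias. The log2 ratio of Pou5f1, -6.35, lay at percentile 0.95 of 1158 genes of like abundance, but Pou5f1 was picked in a search of 60 sets. Cells of Day 4 cannot be told apart either: the plate lay at 0.547 of the way to Day 4 but also at 0.474 of the way to Day 2. Pou5f1 was at 12.64 to 24.37 CPM on Day 4 plates and at 0.144 CPM here, but 0 of 78 cells allows up to 4.69%, and 1 Day 4 plate had 3.92%. The test of a later day was run in 4 forms with differing outcomes: the first put the plate at 1.29 of the way to Day 4 and 0.585 to Day 5, the second judged Days 5 and 6 alone and the third Days 4 and 5 together.

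With all reads used, Egfp reads stood in 25.2% of the kept Day 2 cells of the main experiment and in 0 of 75 kept pilot cells, which allows up to 4%. Of 1217 genes of like share and level in the main cells, 2.22% were at 0 pilot cells. Transcription alike in both experiments would thus seldom give this pattern. But Egfp was tested after its 0 pilot cells had been seen, with no correction for that choice, so this explanation is not excluded. Reads carried over from the Day 5 and Day 6 plates stay open, since counts were too few. Of 44 genes without a Day 2 pilot read, 6 (13.6%) had fewer Day 2 main reads than the lowest carry-over predicts, such as Celf3 with 0 reads against 18.2. But reads of a cell are copies of few molecules, and counted in cells the predictions for these 6 genes were 0.692 to 4.02 cells, and 0 of the 44 genes (0%) fell short. An earlier form of that test, on reads, found 5 of 37 such genes. A reporter active in the main experiment alone was not tested and could also be the source.

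At 10000 reads per cell, Stmn2 reads stood in 45.1% of main and 12.2% of pilot Day 2 cells, before its fall to Day 4. Carry-over from Day 6 plates was argued against, since the Day 2 level of Stmn2 was 6.56% of its eGFP++ level and that of Egfp 0.138%, a ratio of 47.6. A few neurons among the Day 2 cells were argued against as well, since they would bring their other abundant transcripts alike. Over 21 such pan-neuronal genes the median Day 2 share of the eGFP++ level was 0.12 of that of Stmn2 in the main experiment (upper 95% limit 0.363) and 0.0172 in the pilot experiment (0.261). The test tried first, the rho of Stmn2 with the other pan-neuronal genes across Day 2 cells, gave at most 0.116 and decides nothing, since these genes had few reads. Transcription of Stmn2 in Day 2 cells stays as a hypothesis, found and tested on the same data.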

How the results depend on the processing

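Counting cells with a read, leaving out 3 plates and each experiment alone with plates as units were added after the data had been seen. With 2 sums per group at this depth and spread, changes of 4-fold or less were seldom called in simulated data. The next larger thinning depth was not run for shares and relations, since 10000 reads is the top of the series. Leaving out a sum leaves 1 for its group, which is assumed to vary like the other groups. Plates of a day share a culture, so fits with plates as units understate the spread. Comparisons are listed as Day 3 against 2, 4 against 3, 5 against 4, 6 against 5, 6 against 2 and eGFP++ against Day 6, where edgeR called 8, 0, 0, 0, 134 and 5 genes.

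DESeq2 called 166, 155, 186, 129, 2035 and 514 genes, cells with a read 484, 46, 282, 255, 3540 and 151, and plates as units 246, 34, 72, 39, 2977 and 235. The main experiment alone gave 798, 82, 121, 159, 3759 and 436 and the pilot alone 130, 151, 94, 18, 393 and 105. Thinned cells gave 31, 18, 663 and 27 in the first, the third, the fifth and the sixth comparison, and a fit of the 2 groups alone 3, 508 and 21 in the first, the fifth and the sixth. For Day 6 against 2 the count was 40 with 2000 genes per cell and 76 without 3 plates. For eGFP++ it was 3 with 1000 genes, 3 with 2000 genes, 3 without the filter on low counts, 3 without the experiment term and 2 without 3 plates. Leaving out 1 sum gave 0 to 38, 0 to 8, 0 to 15, 0 to 0, 8 to 156 and 0 to 761 genes. The cause was not tested for any of these. The 3 plates held Day 3 and Day 4 cells only. Leaving them out thus moved Day 6 against 2 and eGFP++ only through the shared fit. DESeq2 and plates as units called all 134 genes of Day 6 against 2 again, thinned cells 131 and cells with a read 119.

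Camera called 7, 5, 9, 7, 16 and 9 lists; with an estimated correlation it called 1, 0, 0, 0, 9 and 1, and fry called 3, 0, 0, 0 and 4 in all but the fifth. Cells with a read gave 11, 17 and 17 lists in the second, the third and the fourth comparison, and without 3 plates the second had 1. Markers passed 14 of 18 times, and 0 to 0 without either experiment, where the few orders of 5 days leave little room to pass after adjustment. Agreement among genes of at least 20 CPM was 0.328, 0.177, 0.264, 0.419, 0.773 and 0.204. Cells with a read reversed glycolysis on Day 5 against 4 (-0.54) and interneuron factors on Day 6 against 5 (-0.38), and for Day 6 against 2 Phox2a (-2.66), Stra8 (-0.71), Hsp90aa1 (0.0326) and Mki67 (-0.80). The main experiment alone reversed Elavl3 on Day 3 against 2 (-2.07) and Sox1 in eGFP++ (-2.91). The cause was not tested. Of the other values, 802 of lists, 69 of markers and 7801 of named genes stayed on the same side of the threshold. Those that passed in both settings also kept their direction, while a change of direction was not counted where neither setting passed. In the same order 81, 3 and 71 became weaker, and 39 of lists and 671 of named genes stronger. With 1 sum left out, 2349 values of named genes stayed the same, 135 became weaker and 20 stronger. The 3 weaker markers were Pax6 at 5000 reads (adjusted p = 0.0534), and Pax6 and Olig2 with 2 reads (0.0523 for both).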

Other observations

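Levels of some genes of other lineages, picked after their values were seen, are given here. Their lists did not pass, nor did the genes over all genes; Slc1a2, Hoxb9 and Cdh1 passed adjusted over their list alone. Sox10, a factor of neural crest and of oligodendrocytes, was at 15.6 CPM in eGFP++ cells against 1.19 CPM in unselected Day 6 cells of the main experiment, and at 31.4 against 0.0638 CPM in the pilot experiment (fitted log2 change 8.67 ± 3.45, edgeR adjusted p = 0.743). Slc1a2, a glutamate transporter of astrocytes, went from 0.294 to 33.3 CPM and from 0.0203 to 37.9 CPM between Day 2 and Day 6 (adjusted p = 0.0559). Hoxb9, a thoracic Hox gene, went from 0.196 to 120 CPM in the main experiment and from 0 to 14.2 CPM in the pilot experiment (adjusted p = 0.0884). Cdh1, the cadherin of epithelia, was at 0.36 CPM in eGFP++ cells against 28.4 CPM and at 4.46 against 196 CPM (adjusted p = 0.116).

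The levels of 2 retinoic acid genes are given without a test of their timing. Stra8, a gene of germ cells that responds to retinoic acid, went from 47.7 CPM on Day 2 to 3291 CPM on Day 3 in the main experiment and from 22.4 to 1875 CPM in the pilot experiment, with a fitted log2 change of 6.17 that did not pass (adjusted p = 1), and stood at 112 and 232 CPM on Day 6. Cyp26a1 was at 324 CPM on Day 3 and at 97.4 CPM on Day 6 in the main experiment, and at 227 and 82.1 CPM in the pilot experiment.

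The spike-in share was higher on Day 6 than on Day 2 also among well-covered cells. Among cells with at least 2000 detected genes its median was 2.53% on Day 2 and 13.04% on Day 6 in the main experiment, a ratio of 5.16, and 3.07% and 12.5% in the pilot experiment, a ratio of 4.06. These ratios came from a test of wells with little RNA that was run and then left out of the tests of explanations, since those were kept to 3 patterns. Levels in CPM are shares of the gene reads, so a fall in total RNA per cell would not show in them.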
